A study of Mus musculus with 4 samples.

How the data were processed

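RNA sequencing libraries were made from total RNA of 46C mouse embryonic stem cells in 2 states, with 2 libraries of ESCs in 2i medium and 2 libraries of rfISCs in PIF medium, per the labels. The authors deposited 1 table with a row per transcript. It held 160308 transcripts, of which 142434 had an Ensembl ID and 17874 were assembled transcripts with the ID prefix MSTRG. The values of the 4 libraries were deposited by the authors as estimated counts of reads, which hold decimals and were not scaled between libraries. The table also gave TPM for each library and the authors' mean TPM of each group, per the file headers. The authors deposited a fold change as the ratio of rfISCs to ESCs, its log2, a p-value and an adjusted p-value for each transcript. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm9 without saying what each was used for. The quantification tool, the assembler, the annotation and the authors' test were not given in the sources used here. Coordinates are not reported, since the build of the table could not be settled.

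The estimated counts of all transcripts with the same gene name were summed for each library and rounded to whole numbers, which gave 52327 gene names. The 3382 transcripts with a blank gene name took no part in library sizes or tests. They held 1.58% and 1.62% of the counts of the ESCs libraries and 1.27% and 1.22% of those of the rfISCs libraries. Total counts were 19243701 and 21517544 in the ESCs libraries and 21499590 and 23780989 in the rfISCs libraries. Intervals and floors given for low counts cover counting error alone. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

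Genes were kept by filterByExpr with its default minimum count of 10, which left 16355 genes and removed 35972. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling on all 4 libraries and the group as the 1 model term. A gene with a Benjamini-Hochberg adjusted p under 0.05 was counted as changed. CPM values are counts scaled to the TMM-corrected library size, given as mean ± SD over 2 libraries. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound. A ratio with 1 to 3 counts in a group is given with an exact conditional 95% interval. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot go below p = 0.333, so single genes rest on the model fitted across genes.

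Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 26 lists. Beside it, camera was run with the correlation estimated from the data, which rests on few residual degrees of freedom, and fry on the same fit. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names 3 kinds of genes. The first kind is the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM, groups that did not overlap and a symbol that is not a numbered clone. The second kind is 14 genes of pluripotency and its exit, whatever their result. The third kind is up to 4 called members of each list, the 2 with the largest rise and the 2 with the largest fall. It gave 115 genes, some named under more than 1 kind, and a few of them are not reported here. Other genes named in the closing section were chosen after their values were seen. The lists share members. Genes of near-identical families (Zscan4, Usp17l, Rhox, Pramel), genes with many processed pseudogenes and mitochondrial genes with nuclear copies are uncertain, since the division of their reads was made by the authors' unnamed tool. Whether the counting used strand was not given, so overlapping and antisense genes are uncertain too.

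Replicates were compared by a chi-square test over genes with at least 20 counts. The chi-square per degree of freedom was 6.69 for the ESCs pair and 4.53 for the rfISCs pair, above the sampling noise of 1 library counted again. The tests were checked on simulated counts for the comparison of rfISCs against ESCs, with 200 of 16355 genes changed. edgeR recovered 56.7% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 77.3% of those changed 4-fold, with 15 false calls. DESeq2 recovered 50.7%, 65.7% and 69.7% with 7 false calls. Limma on log2(CPM + 1), which is not the limma on TPM used below, recovered 53.7%, 70.1% and 71.2% with 13 false calls. Simulated means came from the ESCs libraries, and changed genes lost to a filter counted as missed. The simulation changed a far smaller share of genes than the 53.7% called in the data, so these rates do not carry over to the data.

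Alternatives were DESeq2's size factors within edgeR, library totals, no filter, the replicate number as a block, each library left out, counts thinned to the shallowest library, the DESeq2 test (DESeq2 1.42.0), limma on the deposited TPM with pseudocounts of 1 and 0.1 and with no filter, edgeR's glmTreat against a fold of 1.5, and an adjusted p under 0.01. One alternative, Ensembl transcripts alone, was added after the data were seen. Gene classes and chromosomes came from GENCODE M21 by gene symbol, which matched 97.5% of the tested genes, and were used in the closing section.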

Results

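Gene expression was measured by RNA sequencing in 46C cells, a mouse embryonic stem cell line that carries a GFP reporter at the Sox1 gene. The 2 ESCs libraries came from cells in 2i medium, which holds inhibitors of MEK and GSK3 and keeps cells in the naive state, and served as the control. The 2 rfISCs libraries came from cells in PIF medium, which were held between the rosette stage, when the epiblast becomes polarised around a lumen, and the later formative stage. Total counts were 19243701 and 21517544 in the ESCs libraries and 21499590 and 23780989 in the rfISCs libraries. The comparison asked how the rfISCs state differs from the naive state across genes.

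Genes of the naive state were lower in rfISCs and genes of the early post-implantation epiblast were higher. The nuclear receptor gene Esrrb fell 4.78-fold, from 859 ± 37.8 CPM in ESCs to 180 ± 2.75 CPM in rfISCs (TMM-scaled counts, mean ± SD, n = 2 libraries per group). The DNA methyltransferase gene Dnmt3b rose 5.66-fold, from 90.7 ± 4.40 to 513 ± 5.37 CPM. The core factor gene Pou5f1 was abundant in both groups, at 1069 ± 17.6 CPM in ESCs and 546 ± 6.92 CPM in rfISCs. In all, edgeR's quasi-likelihood test called 8783 of 16355 tested genes, or 53.7%, of which 4472 rose and 4311 fell. Among these, 1953 rose at least 2-fold and 1642 fell at least 2-fold. The split depended on the scaling. With TMM it was 50.9% higher, and with library totals, which change the scaling alone, 59.2% (5185 higher and 3572 lower). Limma on log2(TPM + 1), which changes the test, the measure and the filter as well, called 4419 genes higher and 2240 lower, or 66.4% higher. Replicates correlated at 0.994 in ESCs and 0.995 in rfISCs across genes, which are not independent replicates, and libraries of different groups at 0.936 to 0.940.

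**Figure D1:**
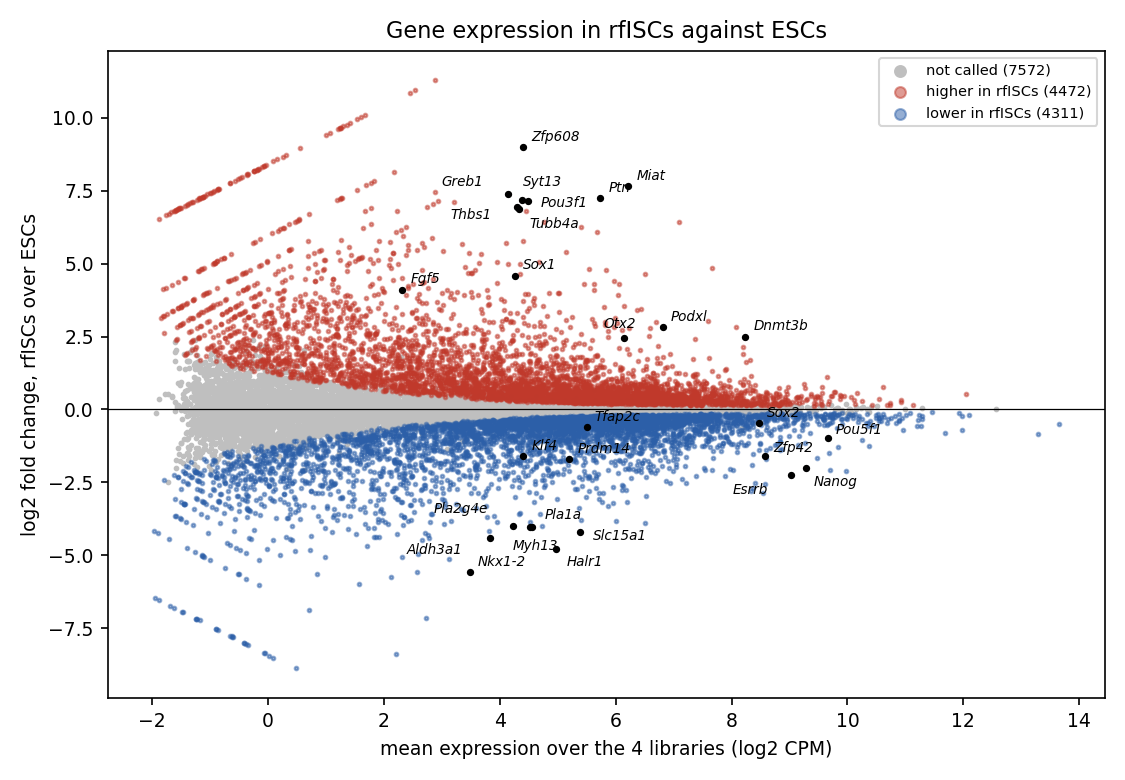
Each point is a gene, plotted by its mean expression over the 4 libraries (log2 CPM) and its log2 fold change of rfISCs over ESCs, with 4472 genes called higher in red, 4311 called lower in blue and the others in grey. Named genes include Pou3f1 and Dnmt3b among the rises and Nanog and Esrrb among the falls. The straight lines of points at the left are genes with few counts in a group, whose fitted fold changes depend on the prior count.

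The largest rises among genes of at least 10 CPM were in Zfp608, the long non-coding RNA Miat, Greb1, the growth factor gene Ptn, the synaptotagmin gene Syt13, the POU factor gene Pou3f1, the thrombospondin gene Thbs1 and the tubulin gene Tubb4a. Zfp608 had 3 counts in the ESCs libraries together and 1938 in rfISCs, a ratio of 547 with a 95% counting interval of 187 to 2653. Miat went from 0.746 ± 0.642 to 148 ± 7.78 CPM, and Ptn from 0.674 ± 0.490 to 106 ± 6.52 CPM. Pou3f1, a transcription factor of the formative epiblast and of neural cells, rose 141-fold to 44.4 ± 0.864 CPM. Greb1 rose 167-fold, Syt13 144-fold, Thbs1 124-fold and Tubb4a 118-fold. Among the largest falls were those of the homeobox gene Nkx1-2, the long non-coding RNA Halr1, Aldh3a1, the peptide transporter gene Slc15a1, the myosin gene Myh13 and the phospholipase genes Pla1a and Pla2g4e. Nkx1-2 fell 47.3-fold from 21.8 ± 10.9 CPM, Halr1 27.7-fold from 60.3 ± 3.90 CPM and Slc15a1 18.3-fold from 79.4 ± 3.39 CPM. Aldh3a1 fell 21.1-fold, Myh13 16.5-fold, Pla1a 16.3-fold and Pla2g4e 15.9-fold. Adjusted p-values from edgeR's quasi-likelihood test for these genes ranged from 1.74e-08 for Zfp608 to 6.93e-06 for Nkx1-2. Low ESCs counts set several of these folds, with 2 and 1 counts in ESCs replicates 1 and 2 for Zfp608, 2 and 6 for Greb1, 9 and 2 for Syt13, 22 and 6 for Miat and 6 and 21 for Ptn. The log2 fold change of Miat, 7.67, was 8.95 without ESCs replicate 1 and 6.93 without ESCs replicate 2, and without the latter it was 8.31 for Ptn (7.25 with both), 8.26 for Greb1 (7.38), 6.39 for Syt13 (7.17, and 8.66 without ESCs replicate 1) and -4.93 for Nkx1-2 (-5.57).

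The naive pluripotency list moved down nearly as a whole. Of its 27 members, 23 fell, 2 rose and 2 did not pass, and 24 fell when adjusted over the list alone. The largest falls in it were in the T-box gene Tbx3, 6.75-fold from 120 ± 0.837 CPM, and in the threonine dehydrogenase gene Tdh, 6.44-fold from 573 ± 70.0 CPM. Nanog fell 3.97-fold, from 992 ± 50.4 to 250 ± 6.28 CPM (log2 fold change -1.99, SE 0.0530, edgeR adjusted p = 1.74e-08). Zfp42 fell 3.02-fold and Klf4 3.01-fold, to 190 ± 12.1 and 10.6 ± 2.13 CPM. Prdm14, a regulator of the naive state and of germ cell fate, fell 3.24-fold, from 56.3 ± 8.24 to 17.3 ± 0.249 CPM. The members that rose were Gbx2, 10.5-fold to 10.8 ± 0.237 CPM, and the STAT3 target Socs3, 2.52-fold to 10.3 ± 0.223 CPM. Without ESCs replicate 2 the log2 fold change of Gbx2 was 4.44 in place of 3.39. The list's camera test gave an adjusted p of 2.78e-40, and adjusted p = 0.111 with an estimated correlation.

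The formative and early post-implantation epiblast list moved the other way. Of its 25 members 17 rose, 2 fell and 6 did not pass, with the same counts of rises and falls when adjusted over the list alone. Pou3f1 and the growth factor gene Fgf15 rose most, Fgf15 68.6-fold to 101 ± 4.65 CPM. Otx2, a transcription factor of the formative epiblast, rose 5.44-fold, from 22.1 ± 6.86 to 120 ± 5.73 CPM (log2 fold change 2.44, SE 0.159, edgeR adjusted p = 2.08e-06). Fgf5, a marker of the later epiblast, rose 17.3-fold but stayed low, at 9.42 ± 1.75 CPM against 0.540 ± 0.00783 CPM in ESCs. Slc7a3, an amino acid transporter gene, fell 2.16-fold, and Etv5 fell 1.22-fold. The camera test gave an adjusted p of 1.48e-19, and adjusted p = 0.222 with an estimated correlation.

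**Figure D2:**
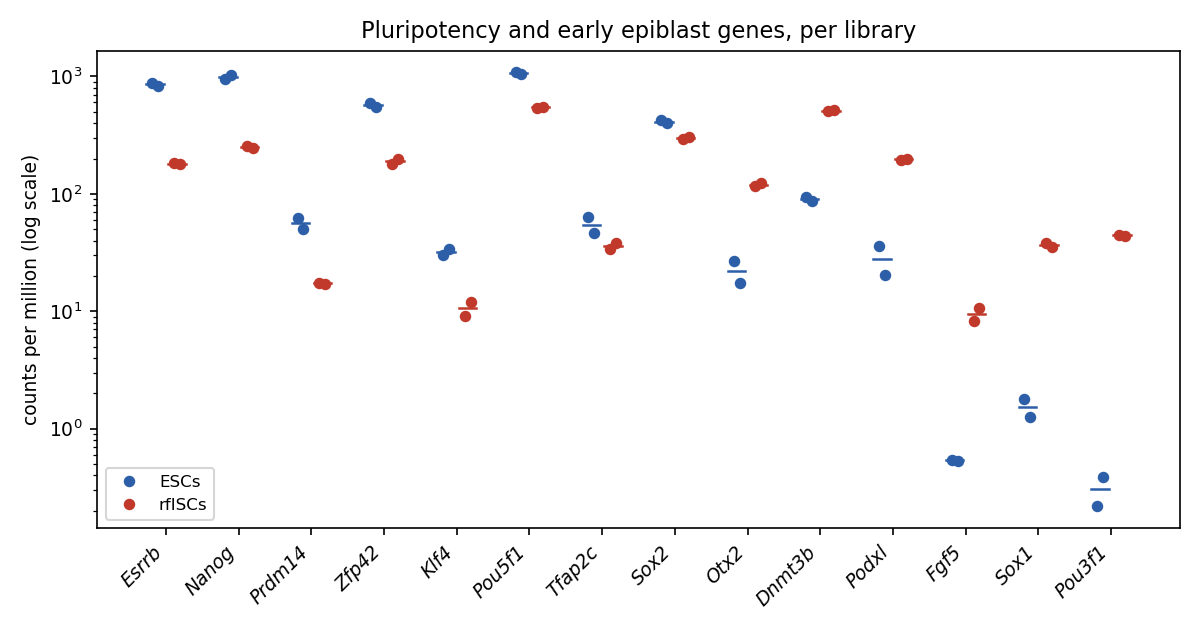
CPM on a log axis for 14 genes of pluripotency and its exit, with a point for each library and a bar at each group's mean, ESCs in blue and rfISCs in red. The 2 rfISCs points of Esrrb, Nanog and Pou5f1 lie below both ESCs points, and those of Otx2, Dnmt3b, Podxl, Fgf5, Sox1 and Pou3f1 lie above.

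Genes shared by naive and primed pluripotency went both ways. Of 16 members of this list 7 rose, 8 fell and 1 did not pass, or 8 and 8 when adjusted over the list alone. The RNA-binding protein gene Lin28a rose 7.17-fold, from 65.9 ± 3.73 to 473 ± 9.36 CPM, and Sall4 rose 1.98-fold. The Nodal co-receptor gene Tdgf1 fell 2.69-fold and L1td1 fell 2.60-fold. Pou5f1 fell 1.96-fold (edgeR adjusted p = 2.18e-07) and Sox2 fell 1.39-fold, from 413 ± 19.2 to 298 ± 8.07 CPM (edgeR adjusted p = 8.19e-05). The camera test did not call the list (adjusted p = 0.405).

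The rosette polarity and lumen formation list was split, with 10 of 24 tested members higher, 8 lower and 6 not passing, both over all genes and adjusted over the list alone. With library totals 10 rose and 5 fell, and with limma on TPM 11 of 23 rose and 5 fell. Podxl, which encodes the anti-adhesive sialomucin podocalyxin of the lumen surface, rose 7.06-fold, from 28.0 ± 10.9 to 197 ± 0.884 CPM (log2 fold change 2.82, SE 0.189, edgeR adjusted p = 2.55e-06). Sytl2, a gene of vesicle traffic, rose 10.9-fold to 1.17 ± 0.103 CPM, from 1 and 3 counts in ESCs replicates 1 and 2 (log2 fold change 3.44, and 4.28 without ESCs replicate 2). The tight junction genes Cldn4 and Cldn3 fell 5.75-fold and 3.92-fold, Cldn4 from 208 ± 20.4 to 36.2 ± 0.198 CPM. The list's median log2 fold change was -0.01 with TMM, 0.07 with library totals and 0.19 with TPM, and its mean was 0.27. Camera did not call it (adjusted p = 0.661). The epithelial list was split too, with 7 of 22 members higher, 7 lower and 8 not passing, and the same rises and falls when adjusted over the list alone (camera adjusted p = 0.405), or 7 higher and 4 lower of 21 with limma on TPM. The keratin genes Krt18 and Krt8, which have many processed pseudogenes, rose 8.61-fold and 7.86-fold, to 30.8 ± 0.816 and 37.9 ± 1.31 CPM.

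Genes of the germ line showed no common direction. Of 24 tested members of the primordial germ cell and germline list 5 rose, 8 fell and 11 did not pass, or 6 and 9 when adjusted over the list alone. Kit, the receptor gene of stem cell factor, fell 3.36-fold, from 129 ± 4.79 to 38.2 ± 0.282 CPM, and the germ cell gene Dazl fell 3.69-fold to 2.47 ± 0.259 CPM. Tfap2c, a transcription factor gene of germ cell specification, fell 1.52-fold, from 54.6 ± 11.9 to 35.7 ± 2.93 CPM (edgeR adjusted p = 0.00468). The homeobox genes Rhox9 and Rhox6, near-identical family members whose reads may be shared, rose 7.04-fold and 6.14-fold, to 5.28 ± 0.157 and 6.23 ± 0.893 CPM. The list's median log2 fold change was 0.06 and its mean -0.01, and camera did not call it (adjusted p = 0.405).

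Genes of the 2-cell-like state, a rare state in naive cultures, fell together. All 11 tested members of this list fell, also when adjusted over the list alone, and their summed level dropped from 64.2 ± 4.53 to 4.75 ± 0.378 CPM. Most of them were low in rfISCs and passed the count filter through the ESCs libraries, so they could only fall. The number of falls and the list's test were therefore partly set by the filter. Of 21 listed members 17 were in the data. Those of them not tested were low in both groups, such as Tcstv3 (0.404 CPM in ESCs and 0.291 CPM in rfISCs) and Tcstv1 (0.121 and 0.0415 CPM). Zscan4a fell 62.9-fold from 5.85 ± 0.321 CPM. Usp17lb had 68 counts in the ESCs libraries and 2 in rfISCs, a ratio of 0.0249 with a 95% counting interval of 0.00295 to 0.0934. Both belong to families of near-identical genes, so which copy the reads came from is uncertain. The size of these falls rests on few rfISCs counts, 3 and 1 in replicates 1 and 2 for Zscan4a and 2 and 0 for Usp17lb. The camera test gave an adjusted p of 2.61e-05, and adjusted p = 0.222 with an estimated correlation.

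Markers of several other cell types were higher in rfISCs, most of them from low levels. Members with no or few counts in ESCs passed the count filter through the rfISCs libraries, so they could only rise. Of 13 tested neural genes 12 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 2.03e-07, and adjusted p = 0.267 with an estimated correlation). The other listed neural genes were too low to test, the highest being Fabp7 with 0 CPM in ESCs and 0.477 CPM in rfISCs. Sox1, an early marker of the neural lineage and the site of the line's reporter, rose 24.1-fold, from 1.53 ± 0.380 to 36.8 ± 2.09 CPM (log2 fold change 4.59, SE 0.170, edgeR adjusted p = 8.78e-08). Its fold was smaller with Ensembl transcripts alone, as given in the section on processing. The neuronal gene Dcx had no counts in ESCs and 32 in rfISCs, at least 9.02-fold higher. Pax3 had 2 counts in ESCs and 145 in rfISCs, a ratio of 61.3 with a 95% counting interval of 16.7 to 511. Both ESCs counts of Pax3 were in replicate 1. The adhesion molecule gene Ncam1 fell 1.99-fold from 137 ± 11.7 CPM. Of 12 tested trophoblast genes 8 rose, 2 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.267 with an estimated correlation). Of these 12 genes 5 stand in another list. The other listed trophoblast genes were too low to test: Tpbpa, Prl3d1 and Psca were at 0 CPM in both groups. Cdx2 was at 0.170 CPM in ESCs and 0.0915 CPM in rfISCs, Elf5 at 0.0243 and 0.195 CPM and Hand1 at 0.225 and 0.641 CPM. Plac1 had no counts in ESCs and 72 in rfISCs, at least 20.3-fold higher, and Gata3 rose 15.8-fold to 3.32 ± 0.0462 CPM, from 2 and 6 counts in ESCs replicates 1 and 2 (log2 fold change 3.98, and 4.86 without ESCs replicate 2). Tead4 fell 3.74-fold from 57.0 ± 0.822 CPM and the galectin gene Lgals3 fell 4.40-fold. With Ensembl transcripts alone the fall of Tead4 did not pass (edgeR adjusted p = 0.339).

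Fibroblast and mesenchymal genes rose in number while their most abundant member fell. Of 12 tested fibroblast and feeder cell genes 9 rose, 1 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000971, and adjusted p = 0.267 with an estimated correlation). The other listed fibroblast genes were too low to test: Lum, S100a4 and Fap were at 0 CPM in both groups. Col3a1, Postn and Prrx1 were at 0 CPM in ESCs and at 0.291, 0.176 and 0.386 CPM in rfISCs. Tested genes with no counts in ESCs had passed the filter through rfISCs and could only rise. The smooth muscle actin gene Acta2 had no counts in ESCs and 214 in rfISCs, at least 60.4-fold higher, and the proteoglycan gene Dcn had none in ESCs and 31 in rfISCs, at least 8.74-fold higher. Fn1, which encodes fibronectin, fell 2.40-fold, from 1867 ± 111 to 779 ± 30.9 CPM. Of 14 tested mesenchymal genes 7 rose, 2 fell and 5 did not pass, or 10 and 2 when adjusted over the list alone (camera adjusted p = 7.55e-07, and adjusted p = 0.222 with an estimated correlation). With library totals 11 of the mesenchymal genes rose and 1 fell, and with limma on TPM 9 of 13 rose and 1 fell. Cdh11 had 1 count in ESCs and 412 in rfISCs, a ratio of 349 with a 95% counting interval of 62.2 to 13801. The ESCs count of Cdh11 was in replicate 2. Sparc, at 231 ± 1.93 CPM in ESCs and 206 ± 11.5 CPM in rfISCs, passed narrowly (edgeR adjusted p = 0.0429), and did not pass with library totals (0.297), without rfISCs replicate 1 (0.406) or without rfISCs replicate 2 (0.0630).

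Primitive endoderm and primitive streak genes went both ways. Of 15 tested primitive endoderm genes 6 rose, 5 fell and 4 did not pass, or 7 and 5 when adjusted over the list alone and 5 and 2 of 12 with limma on TPM, and camera did not call the list (adjusted p = 0.0759), though it did without rfISCs replicate 1 (0.0465) and without rfISCs replicate 2 (0.0328), but not with an estimated correlation (0.267). The endocytic adaptor gene Dab2 rose 29.1-fold to 8.40 ± 0.337 CPM and the basement membrane collagen gene Col4a2 rose 14.4-fold to 26.1 ± 1.39 CPM. Apoe fell 2.82-fold, from 1209 ± 19.9 to 428 ± 25.5 CPM, and Hnf4a fell 4.01-fold to 1.02 ± 0.0831 CPM. Of 11 tested primitive streak and gastrulation genes 4 rose, 2 fell and 5 did not pass, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.455). Wnt8a rose 22.9-fold to 7.22 ± 1.42 CPM and Foxa2 rose 20.9-fold to 2.25 ± 0.982 CPM, Foxa2 from 1 and 3 counts in ESCs replicates 1 and 2 (log2 fold change 4.38, and 5.23 without ESCs replicate 2). Several primitive streak genes were too low to test. Among them were T (0.410 CPM in ESCs and 0.355 CPM in rfISCs), Mixl1 (0.240 and 0.154 CPM) and Mesp1 (0.203 and 0 CPM). Besides Nkx1-2, the T-box gene Eomes fell 1.85-fold (edgeR adjusted p = 0.0168), a call lost without ESCs replicate 2 (0.0780) and without rfISCs replicate 2 (0.0887).

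Targets of the Wnt and BMP pathways rose more often than they fell. Of 17 tested Wnt/beta-catenin targets 9 rose, 3 fell and 5 did not pass, or 10 and 3 when adjusted over the list alone (camera adjusted p = 0.00877, and adjusted p = 0.267 with an estimated correlation). Besides Wnt8a, the inhibitor gene Dkk1 rose, from no counts in ESCs to 29 in rfISCs, at least 8.18-fold higher. Notum, an inhibitor that inactivates Wnt proteins, fell 3.51-fold from 78.8 ± 13.8 CPM, and Cdx1 fell from 2.498 ± 2.38 to 0.160 ± 0.226 CPM. Without ESCs replicate 1 camera did not call the Wnt list (adjusted p = 0.0872), and without ESCs replicate 2 edgeR did not call Cdx1 (adjusted p = 0.0571), which had 15 and 86 counts in ESCs replicates 1 and 2 and 7 and 0 in rfISCs replicates 1 and 2. Of 13 tested BMP targets 6 rose, 3 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0454, and adjusted p = 0.267 with an estimated correlation). Id2 and Id3, inhibitors of bHLH factors, rose 39.98-fold and 31.3-fold, to 24.9 ± 1.45 and 34.1 ± 4.0001 CPM, while Id4 fell 7.93-fold and Msx2 3.02-fold. The log2 fold change of Id3 was 5.85 without ESCs replicate 1 and 4.38 without ESCs replicate 2, in place of 4.97. The call on the BMP list was lost with the replicate block (adjusted p = 0.245), with library totals (0.0570), without ESCs replicate 1 (0.262) and without ESCs replicate 2 (0.148).

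Targets of FGF/ERK signalling, which 2i medium blocks, and of Nodal/Activin signalling were not called as lists in the main test, but were in some alternatives. Of 20 tested FGF/ERK targets 12 rose, 4 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0752). The early response gene Egr2 rose from 0.0972 ± 0.137 to 14.3 ± 3.67 CPM and Myc from 0.610 ± 0.786 to 5.30 ± 0.893 CPM. Ier3 fell 1.54-fold and the FGF antagonist gene Il17rd fell 2.70-fold. Egr2 had 0 and 4 counts in ESCs replicates 1 and 2 and Myc 1 and 24. The log2 fold change of Myc, 3.06, was 2.18 without ESCs replicate 1 and 6.46 without ESCs replicate 2, and that of Egr2, 7.04, was 6.15 without ESCs replicate 1, while no ESCs counts of Egr2 remain without ESCs replicate 2. With the FGF/ERK list the alternatives went both ways around the threshold, from 0.0111 with no filter to 0.0880, and it was called without ESCs replicate 1 (0.0446), without ESCs replicate 2 (0.0191), without rfISCs replicate 1 (0.0306), without rfISCs replicate 2 (0.0326), with the replicate block (0.0258) and with Ensembl transcripts alone (0.0210), but not with an estimated correlation (0.267). Of 14 tested Nodal/Activin targets 3 rose, 8 fell and 3 did not pass, or 5 and 8 when adjusted over the list alone (camera adjusted p = 0.0617), and camera called this list with no filter (0.0243) and with Ensembl transcripts alone (0.0223), but not with an estimated correlation (0.267). Lefty2, a target and inhibitor of Nodal, fell 3.73-fold, from 516 ± 53.02 to 138 ± 1.58 CPM, like Tdgf1, while Fst, which encodes the Activin antagonist follistatin, rose 9.89-fold to 32.6 ± 1.03 CPM.

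The genes of DNA methylation were split, and imprinted genes rose more often than they fell. Of 19 genes of the DNA methylation machinery 7 rose, 6 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.960), with a median log2 fold change of 0.03 and a mean of -0.09. Besides Dnmt3b, the dioxygenase gene Tet3 rose 2.74-fold, from 22.2 ± 1.53 to 60.9 ± 0.961 CPM. Tet2 fell 5.73-fold, from 252 ± 8.72 to 44.0 ± 2.79 CPM, along with Prdm14. Of 31 tested imprinted genes 19 rose, 7 fell and 5 did not pass, or 20 and 8 when adjusted over the list alone (camera adjusted p = 1.09e-09, and adjusted p = 0.222 with an estimated correlation). The non-coding RNA H19 rose 86.8-fold, from 3.07 ± 0.948 to 270 ± 6.01 CPM, and its neighbour Igf2, a growth factor gene, rose 77.2-fold, from 1.10 ± 0.453 to 83.8 ± 1.45 CPM. Plagl1 fell 4.198-fold, from 94.0 ± 29.3 to 22.4 ± 2.66 CPM, and Phlda2 fell 2.05-fold.

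**Figure D3:**
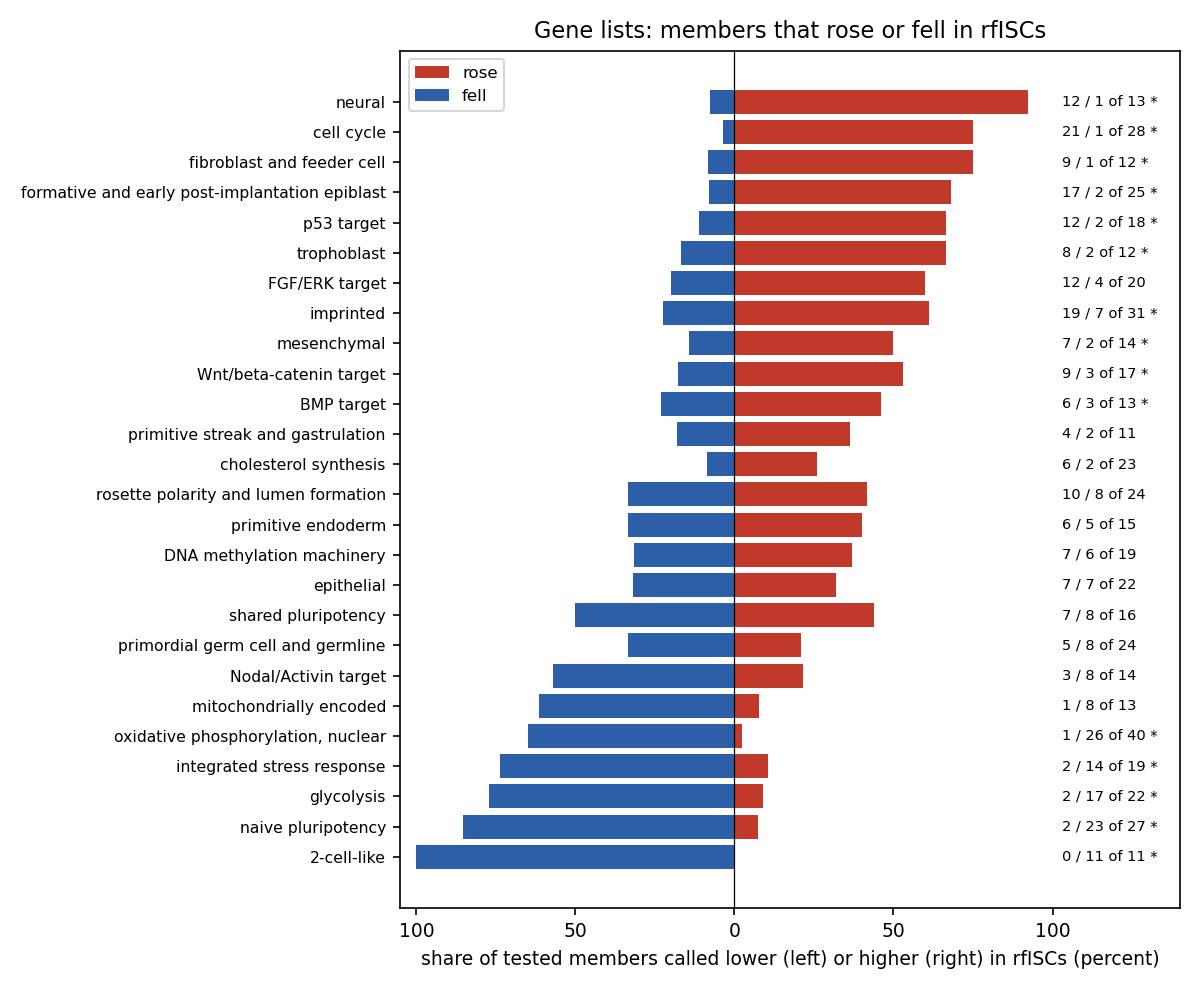
For each of the 26 gene lists the bars give the percent of tested members called higher in rfISCs (red, to the right) and lower (blue, to the left) by edgeR at an adjusted p under 0.05. The numbers at the right are rises and falls of the members tested, and a star marks the 15 lists that camera called at its preset correlation. With an estimated correlation 0 lists were called.

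Genes of glycolysis and nuclear genes of oxidative phosphorylation were lower in rfISCs, most by small steps. Of 22 glycolysis genes 17 fell, 2 rose and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 3.38e-06, and adjusted p = 0.267 with an estimated correlation). The phosphofructokinase gene Pfkp fell 4.26-fold, from 1339 ± 3.63 to 314 ± 8.06 CPM, and Pdk1 fell 2.85-fold. The glucose transporter gene Slc2a1 rose 1.48-fold and the lactate transporter gene Slc16a3 rose 1.51-fold. Of 40 nuclear genes of oxidative phosphorylation 26 fell, 1 rose and 13 did not pass, or 27 and 1 when adjusted over the list alone (camera adjusted p = 0.00390, and adjusted p = 0.283 with an estimated correlation). Its median log2 fold change was -0.24 with TMM, -0.15 with library totals and -0.07 with TPM. The number of falls depended on the scaling, with 16 lower and 2 higher with library totals and 13 lower and 3 higher with limma on TPM. Cox5a and Atp5c1 fell 1.58-fold each, and Ndufa2 rose 1.22-fold (edgeR adjusted p = 0.0203), a call lost without rfISCs replicate 2 (0.202). Of 13 mitochondrially encoded genes 8 fell, 1 rose and 4 did not pass, or 9 and 1 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0824). With library totals 6 fell and 1 rose, and with limma on TPM 3 fell and 0 rose. At the preset correlation the list was called with the replicate block (0.00559), with no filter (0.0141), without ESCs replicate 1 (0.000849), without ESCs replicate 2 (0.0416), without rfISCs replicate 2 (0.00678) and with Ensembl transcripts alone (0.0220), and it was not called with an estimated correlation (0.595). mt-Co3 went from 153 ± 56.5 to 74.2 ± 17.1 CPM, mt-Nd4l from 19.3 ± 9.47 to 10.3 ± 3.67 CPM and mt-Nd3 from 20.9 ± 3.93 to 33.7 ± 9.99 CPM. The mt-Nd4l libraries of the groups overlapped, and its call was lost with library totals (edgeR adjusted p = 0.0552), without ESCs replicate 2 (0.174), where its log2 fold change was -0.30 in place of -0.92, and without rfISCs replicate 2 (0.112). That of mt-Nd3 was lost without rfISCs replicate 1 (0.0990).

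Genes of the integrated stress response were lower in rfISCs, and p53 targets and cell cycle genes were higher. Of 19 tested stress response genes 14 fell, 2 rose and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 2.14e-11, and adjusted p = 0.267 with an estimated correlation). The stress regulator gene Nupr1 fell 13.7-fold, from 79.1 ± 12.3 to 5.77 ± 0.246 CPM, and the glutathione-degrading enzyme gene Chac1 fell 8.99-fold. Ddit4 rose 1.46-fold, and the cystine transporter gene Slc7a11 rose 1.94-fold (edgeR adjusted p = 0.00871), a call lost without rfISCs replicate 2 (0.0947). Of 18 tested p53 targets 12 rose, 2 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000109, and adjusted p = 0.267 with an estimated correlation). The antiproliferative gene Btg2 rose 4.52-fold to 174 ± 2.48 CPM and Perp rose 4.01-fold, while Sesn1 fell 1.39-fold. The cell cycle inhibitor gene Cdkn1a was at 175 ± 5.05 CPM in ESCs and 154 ± 6.74 CPM in rfISCs (edgeR adjusted p = 0.0269), and did not pass with library totals (0.184), without rfISCs replicate 1 (0.276) or without rfISCs replicate 2 (0.0656). Of 28 cell cycle genes 21 rose, 1 fell and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00306, and adjusted p = 0.267 with an estimated correlation). Most of these steps were small, with a median log2 fold change of 0.23 with TMM, 0.32 with library totals and 0.43 with TPM. The cyclin genes Ccne1 and Ccne2 rose most, 2.04-fold and 2.01-fold, to 134 ± 7.16 and 27.6 ± 0.115 CPM. Cdk2, the kinase that cyclin E binds, was at 122 ± 0.839 and 107 ± 6.32 CPM (edgeR adjusted p = 0.0310), and did not pass with library totals (0.186), without rfISCs replicate 1 (0.0611) or without rfISCs replicate 2 (0.313). Cholesterol synthesis genes were not called as a list, with 6 of 23 higher, 2 lower and 15 not passing, also when adjusted over the list alone (camera adjusted p = 0.405). With library totals 12 of them rose and 2 fell, and with limma on TPM 14 rose and 2 fell. Hmgcs1 rose 1.69-fold, while Tm7sf2 fell 1.85-fold and Ebp 1.68-fold.

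The authors' deposited table compared single transcripts, in which 3740 were marked as changed, 2202 higher and 1538 lower in rfISCs, each at least 5.001-fold. These marks belonged to 2755 gene names. For single genes, the transcript with the highest TPM over both groups was taken, among those with enough counts, and other isoforms were left out. In the authors' deposited table the Pou3f1 transcript was 149-fold higher, that of Podxl 7.28-fold, that of H19 88.3-fold and that of Fgf5 27.3-fold. Those of Pou5f1, Nanog, Esrrb, Zfp42 and Otx2 were not marked, with that of Otx2 at 4.78-fold. Yet their adjusted p-values from the authors' unnamed test were at most 8.33e-39, the value of Otx2. In all, 10924 transcripts had an adjusted p under 0.05 in that test, and the unmarked ones among them changed at most 4.998-fold. For 2729 of the marked transcripts the summed gene was called in the same direction. For 551 the gene was not called, for 306 it was called in the opposite direction, 11 had a gene that was not tested and 143 had no gene name.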

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

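Transcripts with no gene name took no part in the comparisons between genes, and no explanation was tested for them. Of these transcripts, 11 were marked higher in rfISCs and 132 lower in the authors' deposited table, which is a signal in data that the gene-level results leave out. The transcript MSTRG.26613.1 had 64.3 and 67.6 counts in the ESCs libraries and 427 and 421 in the rfISCs libraries. MSTRG.2294.1 had 1895 and 8627 counts in the ESCs libraries and 147 and 101 in the rfISCs libraries. Among the 143 marked transcripts without a name, 21 had ESCs replicates at least 3-fold apart, and 17 of these were higher in ESCs replicate 2. Both examples were chosen after their values were seen.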

How the results depend on the processing

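Of the alternatives, Ensembl transcripts alone was chosen after the data were seen. Counts of called genes, 8783 in the main test, stayed within 1.5 times of it with DESeq2's size factors in edgeR (8787), library totals (8757), no filter (9256), thinned counts (8659), the DESeq2 test (7035), Ensembl transcripts alone (6305) and an adjusted p under 0.01 (6491). Of the genes called in the main test, 8750 kept call and direction with DESeq2's size factors, 8044 with library totals, 6940 with DESeq2 and 6147 with Ensembl transcripts alone. Fewer did with limma on TPM: 5756 with a pseudocount of 1, 5656 with one of 0.1 and 4631 with no filter. Limma on log2(TPM + 1) called 2240 genes lower, 902 of them at least 2-fold, and with a pseudocount of 0.1 these were 2182 and 1079. With no filter on TPM it called 5219 genes, with 1734 lower, 1249 at least 2-fold higher and 796 at least 2-fold lower. Limma on TPM changed the test, the measure, the filter and the scaling together and moved the median gene by 0.16 on the log2 scale, so the source of its fewer falls was not told apart. Library totals, which changed the scaling alone, gave 5185 genes higher and 3572 lower and moved the median gene by 0.08. A test against a fold of 1.5 called 3592 genes, 1920 higher and 1672 lower, fewer by its construction. Camera with an estimated correlation called 0 of 26 lists, where the preset correlation called 15 and fry, which tests a list by itself, called 23. Leaving out each library in turn gave 6813 to 9284 called genes, 3446 to 4791 higher, 3367 to 4493 lower, 1676 to 2098 at least 2-fold higher, 1482 to 1653 at least 2-fold lower and 15 to 18 lists; the lone library was then assumed to vary like the other group. Across genes, the difference in log2 CPM between ESCs replicates 1 and 2 correlated at 0.00650 with that between rfISCs replicates 1 and 2. With a single difference per group this cannot exclude that same-numbered libraries shared a day or batch. The fit with the replicate block called 8825 genes, 4501 higher and 4324 lower, of which 8575 were shared with the main test. Of the 115 genes that the rule for named genes gave, all called in the main test, 102 kept their call in the alternatives run for genes, 13 lost it in at least 1 and 0 changed direction, though Dcn and Dkk1 gave no value without rfISCs replicate 2, where 113 genes were tested. Limma on TPM, the test against a fold of 1.5 and the adjusted p under 0.01 were not among the alternatives run for these genes. The DESeq2 test lost 10 calls, among them Eomes (adjusted p = 0.0822), Cdx1 (0.165), Myc (0.108), Sparc (0.0833), Ndufa2 (0.0779), mt-Nd4l (0.256), mt-Co3 (0.0504), Cdkn1a (0.0574) and Cdk2 (0.0782). Ensembl transcripts alone lost 8, among them Tead4 (0.339), Cdx1 (0.0516), Sparc (0.407), Ndufa2 (0.0654), mt-Nd3 (0.0702), mt-Nd4l (0.121) and Cdk2 (0.0549). Library totals lost 4, and leaving out ESCs replicate 2 lost 3, rfISCs replicate 1 lost 5 and rfISCs replicate 2 lost 7. The fold moved by over 1.5 times for 16 genes without ESCs replicate 2, 9 without ESCs replicate 1, 3 without each rfISCs library in turn and 5 with DESeq2. Ensembl transcripts alone moved that of 10 genes, among them Sox1, from a log2 fold change of 4.59 to 3.12, and Fgf5, from 4.11 to 4.78. Over 10 alternatives the adjusted p of the naive list ranged from 1.46e-51 to 7.98e-18, that of the formative list from 4.35e-25 to 2.70e-09, that of the Wnt list from 0.00208 to 0.0872 and that of the BMP list from 0.0141 to 0.262. Depth limits genes with few counts in a group, for which a ratio or a lower bound is given.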

Other observations

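Families of genes with a shared symbol, chosen after the data were seen, were tested with camera over 165 families of at least 10 tested members, and 22 were called, 15 higher and 7 lower, with 0 called at an estimated correlation (lowest adjusted p = 0.844). Of 16 Sox genes, which encode transcription factors, 12 rose and 2 fell (adjusted p = 1.65e-07), and of 30 collagen genes 19 rose and 3 fell (adjusted p = 0.000194). Of 13 cadherin genes (Cdh) 9 rose and 3 fell (adjusted p = 0.00115), among them Cdh2, which encodes N-cadherin and went from 4.201 to 83.4 CPM (log2 fold change 4.31, SE 0.105, edgeR adjusted p = 1.27e-08). The epithelial cadherin gene Cdh1 went from 438 to 373 CPM (log2 fold change -0.23, SE 0.0503, edgeR adjusted p = 0.00386). Of 14 Wnt ligand genes 8 rose and 1 fell (adjusted p = 0.0291). The medians of these 4 families were above 0 with TMM, library totals and TPM.

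Genes of the pluripotency-associated non-coding RNAs (Platr) fell, 13 of 18 with 2 higher (adjusted p = 0.00474), led in level by Platr14, which went from 328 to 122 CPM (log2 fold change -1.43, SE 0.0805, edgeR adjusted p = 8.37e-07). Of 12 Pramel genes, near-identical members of a family with uncertain assignment of reads, 9 fell and 0 rose (adjusted p = 0.0111), among them Pramel13, from 115 to 39.0 CPM. Both medians were below 0 with TMM, library totals and TPM. Median log2 fold changes of protein-coding genes with an average log2 CPM over 3 on the 19 autosomes lay between -0.10 and 0.07, where an extra copy of a chromosome pair in 1 group would give 0.58. Of 8 such genes on the Y chromosome 5 fell and 0 rose, with Ddx3y at 88.5 CPM in ESCs and 57.5 CPM in rfISCs, while the Y pseudogenes Mid1-ps1 (log2 fold change 0.52, edgeR adjusted p = 0.00141) and Gm21742 (0.74, 0.00898) rose.

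The tests in the following paragraphs were chosen after the result was seen, apart from the match on expression for intergenic lncRNA genes and pseudogenes. Non-coding genes and pseudogenes fell more often than they rose: among genes changed at least 2-fold the share that fell was 39.5% of protein-coding genes (exact 95% interval 37.7 to 41.3%), 77.1% of intergenic lncRNA genes (69.7 to 83.4%), 83.8% of pseudogenes (77.7 to 88.8%) and 64.2% of other non-coding genes (57.2 to 70.8%). Genomic DNA in the ESCs libraries would raise all silent genes there, and receptor genes of the nose did tend that way: of 49 tested olfactory receptor genes (Olfr) 15 fell and 0 rose, of 45 vomeronasal receptor genes (Vmn) 19 fell and 0 rose, and all 1116 olfactory receptor genes in the table summed to 159 ± 7.81 CPM in ESCs and 98.6 ± 1.29 CPM in rfISCs (SD, n = 2). An excess of DNA spread evenly over genes is argued against as the source of falls of this size. The mean excess in ESCs over these 1116 genes was 0.0539 CPM per gene (95% interval 0.0288 to 0.0789), and over 353 vomeronasal receptor genes, symbols of pseudogenes left out, 0.0854 CPM (0.0420 to 0.129). The lower quartile of the fall was 1.22 CPM among the intergenic lncRNA genes and pseudogenes and 0.978 CPM among other non-coding genes. These quartiles came from genes picked for a fall of at least 2-fold, and the excess from all receptor genes. The comparison therefore cannot speak against an uneven spread of DNA reads. Among tested genes the median log2 fold change was -0.64 for Olfr and -0.70 for Vmn. It was -0.44 for intergenic lncRNA genes, -0.32 for pseudogenes and -0.15 for other non-coding genes. Of the 1116 genes 897 had no counts in ESCs and 11 had an excess of at least the 1.22 CPM, as had 6 of the 353. Per kb of the longest transcript the excess was 0.0102 CPM for olfactory and 0.00866 CPM for vomeronasal receptor genes, and the lower quartiles were 0.781 and 0.485 CPM. Low expression is argued against, since protein-coding genes matched on mean expression fell in 35.1% of cases, and in 42.2% in the highest of 1000 draws, against 80.7% for intergenic lncRNA genes and pseudogenes together, and in 34.2% and at most 42.5% against the 64.2% of other non-coding genes. Reads shared between pseudogenes and parent genes could not account for the 77.1% among intergenic lncRNA genes, which have no parent gene, but for the 83.8% among pseudogenes a change in the pseudogenes and one in their parents cannot be told apart, since a symbol named the parent gene for 6 of the 155 that fell. Reads of overlapping genes were not tested for. The difference in cell state that the design names may be the source, which was not tested apart from the medium or from RNA selection during library preparation.

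Markers of other lineages were higher in rfISCs, as given above, and may come from other cells in the cultures or from the main cells themselves. Fibroblasts or feeder cells are argued against as the source of the rise of Mmp2, to 39.1 ± 2.22 CPM, since the collagens abundant in such cells, Col1a1, Col1a2 and Col3a1, together reached 5.59 ± 0.0493 CPM in rfISCs (SD, n = 2). These collagens rose from 0.352 ± 0.189 CPM in ESCs, as a small share of fibroblasts would bring, so for the other 8 fibroblast genes that rose such a share and expression in the main cells cannot be told apart, since bulk libraries do not show which cells a transcript came from; of the 12 tested fibroblast genes 2 had at least 10 CPM in ESCs and 5 stand in another list. Whether a lower share of the main cell type raised these markers cannot be decided here. The 2-cell-like list had a median log2 fold change of -3.76 and the neural list one of 4.10, or 3.17 with genes at 0 in ESCs set to their bound. The 2-cell-like state occurs in naive cultures, so its genes can fall with the naive state whatever other cells are present. A subpopulation of differentiating cells and a low level in all cells cannot be told apart, since 12 of 13 neural genes rose in bulk libraries that hold no cell numbers, and 5 of the 13 had at least 10 CPM in ESCs.

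Of the transcripts marked in the authors' deposited table, 857 belonged to genes that the summed counts did not call or called in the opposite direction. Replicates that differ in how reads were divided between isoforms could account for a part: 36 of the 857, or 4.201% (exact 95% interval 2.96 to 5.77%), had replicates at least 10-fold apart with at least 20 counts in the higher one, above the 1.76% among 2729 transcripts whose gene was called in the same direction. All of these transcripts had passed the authors' marking, which may leave out discordant replicates, and gaps under 10-fold were not counted. The share therefore cannot show how large this part is. The limit of 50% used to judge this as the main source was set after the share had been seen, in place of a first version that only asked whether the share exceeded the 1.76%, which it did. For the other 821 transcripts, which did not reach the 10-fold limit, 3 sources cannot be told apart, since reads were not used here. These are replicates that differ by less, a change of isoform use and a steady misassignment of reads between isoforms.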
